A study of Mus musculus with 7 samples.

How the data were processed

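Gene expression was measured on Affymetrix mouse arrays in 7 samples, 4 WT and 3 KO. Per the series' design text, mice carried a Tomato reporter allele of Mex3a together with either a floxed allele (KO) or a wild-type allele (WT), a tamoxifen-inducible Cre active in the gut epithelium and 1 floxed Apc allele. They received 4 injections of tamoxifen and then 2% DSS for 5 days, and adenomas were collected 2 months after DSS ended. Per the labels' protocols, adenomas were dissociated with collagenase, Epcam-positive and Tomato-positive cells were sorted, RNA from 2000 cells was isolated with magnetic beads and amplified over 24 cycles, and 8 µg of cDNA was fragmented and labelled. Amplification from so few cells can add spread between arrays that genotype does not explain.

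The deposited values are log2 levels per probe set, made by the authors with RMA (robust multi-array average, which corrects background, normalizes the arrays together and summarises the probes of a set), per the submitters' processing notes. The version of RMA, and any filter or batch correction, are not given in the sources used here. No genome build applies to the probe set values and none is given in the sources used here. The table held 45141 probe sets with 1 column per array and no column outside the 7 samples. In 19995 probe sets at least 2 arrays carried exactly the same value, which the median step of RMA can produce; such ties make the spread within a group look small for some genes. Scanner files were not analysed here, so the scale and centring were taken as deposited.

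Of the probe sets, 104 were controls, 28898 were paired with 1 gene symbol by the platform annotation, 551 with several and 15692 with none; only those with 1 gene were named. Symbols were checked through the gene numbers of the RefSeq annotation of GRCm38.p6, where 28689 of the probe sets matched and 0 symbols needed an update. That annotation was otherwise used only for which genes neighbour each other. For each of 17097 genes the probe set with the highest mean over all arrays was kept. The lowest 25% of genes by mean level (below 5.28 on the log2 scale) were left out, which left 12822.

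KO was compared with WT in limma (version 3.58.1, R version 4.3.3), with lmFit and eBayes with a trend on mean level, scan batch as a fixed covariate, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Scan batch is given in the labels: batch 1 held 2 WT arrays and 1 KO array, batch 2 held 2 of each. The fit left 4 residual degrees of freedom per gene, and the median SE of a log2 difference was 0.093. Single values and list means were also compared by exact permutation over the 35 splits of the arrays, and the smallest p that test can give is 0.0286. Those splits do not keep scan batch; exchanging arrays only within scan batch leaves 18 arrangements and a smallest p of 0.0556. The differences printed come from the fit with scan batch, and group means and SDs from the values themselves, so the 2 can differ slightly.

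For gene groups, 30 lists with 777 members were fixed before the data were examined, and 584 members were tested. They cover stem cells, Wnt targets, colonocytes, goblet cells, deep crypt and Paneth cells, enteroendocrine cells, tuft cells, DNA replication, mitosis, retinoic acid signalling, PPAR targets, fetal-like epithelium, interferon-stimulated genes, antigen presentation, NF-kB mediators, immediate early genes, the unfolded protein response, p53 targets, glycolysis, cholesterol synthesis, the respiratory chain, ribosomal proteins, leukocytes, fibroblasts, endothelium, enteric neurons, erythroid cells, epithelial identity, sex-linked genes and the MEX3 family. Each list was tested with camera (preset correlation 0.01), which compares its genes with all others, with Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation and fry were alternatives. A camera call with a preset correlation can be too liberal where the genes of a list vary together between arrays.

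The genes named are Mex3a and its paralogs, up to 10 genes per direction past the threshold or, where fewer pass, those of smallest p with a log2 difference of at least 1, and in each list the 4 members with the smallest p; predicted transcripts were counted but not named. This rule was fixed before the data were examined and gave 121 genes. Lgr5, Epcam, Hoxd9, Hoxd11, Hoxd13, Rab25, Lamtor2 and the genes named only as members of neighbouring pairs fall outside it and were chosen after their values were seen. Mex3b falls under the rule but lay below the level filter, so its difference and adjusted p come from a fit over all probe sets. The fit was tested on simulated data with the spread of these arrays, in 10 runs of 12822 genes with 200 changed genes. It recovered 53.9% of genes changed by 0.5 on the log2 scale, 87.6% of those changed by 1 and 98.9% of those changed by 2, and 4.30% of its calls were false. The noise was independent between genes, and with 200 changed genes the adjustment is more lenient than where few genes change. Those shares therefore do not carry over to the real data, where Mex3a, at -1.13, had an adjusted p of 0.142 in limma. A list shifted by 0.15 was found in 10 of 10 runs, with noise independent between genes, so that test does not cover genes that vary together.

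Alternatives fixed before the data were examined were no scan batch term, scan batch as a random block, each scan batch alone, quantile normalization, centring each array on its median, other choices of probe set, other level filters, leaving out each array in turn, array weights, other eBayes settings, a residual component as covariate, other thresholds and other list tests. A term for sex, a fit on the 5 arrays without Y-linked signal, the difference between the 3' and 5' probe sets of Gapdh as covariate, a fit on all probe sets and, for the called lists, leaving out each array with no term for scan batch were chosen after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.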

Results

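The data were 7 Affymetrix expression profiles of tumour cells from the mouse colon. Adenomas arose after tamoxifen-induced recombination of 1 Apc allele in the gut epithelium, followed by dextran sulfate sodium (DSS), a colitis-inducing polymer, in the drinking water. From dissociated adenomas, cells were sorted that carried the epithelial surface protein Epcam and a Tomato reporter driven by the Mex3a promoter. Of the 7 arrays, 4 came from animals with a working Mex3a allele (WT) and 3 from animals in which it was recombined (KO). MEX3A is an RNA-binding protein found in intestinal stem and progenitor cells. The comparison asks how Mex3a-promoter-active adenoma cells differ when the gene itself is lost. The median log2 level over all probe sets was 5.96 in WT replicate 1, 5.97 in WT replicate 2, 5.97 in WT replicate 3, 6.00 in WT replicate 4, 5.96 in KO replicate 1, 5.97 in KO replicate 2 and 5.96 in KO replicate 3. The number of arrays limits the precision. Nothing in the labels says that each array is a separate animal, so the p-values measure the spread between these samples, which may be technical in part.

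Mex3a was lower in all 3 KO arrays than in all 4 WT arrays. On the brighter of its 2 probe sets the log2 level was 7.33 ± 0.22 (SD, n = 4) in WT and 6.18 ± 0.11 (SD, n = 3) in KO, a 2.19-fold lower level with a log2 difference of -1.13 (SE 0.13). The WT arrays read 7.41, 7.38, 7.50 and 7.01 and the KO arrays 6.18, 6.29 and 6.07. The other probe set was 1.52-fold lower, at 6.61 ± 0.30 (SD, n = 4) in WT and 5.97 ± 0.18 (SD, n = 3) in KO, again without overlap. For both probe sets the two-sided exact permutation p was 0.0286, the smallest that the 35 splits of 7 arrays can give. With arrays exchanged only within their scan batch, which leaves 18 arrangements, the exact permutation p was 0.0556 for both, again the smallest possible, so that test cannot fall under 0.05. In the limma fit over 12822 genes Mex3a had the smallest p of all genes, 2.17e-05, with an adjusted p of 0.142. The adjusted p was 0.0455 without WT replicate 4 and 0.0269 with array weights, against a range of 0.0269 to 0.991 over 24 alternatives. Where these probe sets lie relative to the floxed part of the gene is not given in the sources used here.

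Mex3c, a family member that also encodes an RNA-binding protein, went the other way. Its log2 level was 5.71 ± 0.45 (SD, n = 4) in WT and 6.53 ± 0.04 (SD, n = 3) in KO, a difference of 0.87 (SE 0.21) or 1.82-fold. WT replicate 2 stood at 6.37, near the KO arrays, while the other WT arrays read 5.40, 5.47 and 5.58. Both MEX3 family genes tested, Mex3a and Mex3c, passed when adjusted over the list alone (limma, adjusted p = 4.34e-05 and 0.003). That list holds 2 tested genes, among them the deleted gene, so its adjustment leaves Mex3c at its unadjusted p. Over all genes 0 passed, and Mex3c had an adjusted p of 0.388 there. The two-sided exact permutation p of Mex3c was 0.0571, and 0.111 within scan batch. Without WT replicate 2 the adjusted p of Mex3c over all genes was 0.0208, and with the Gapdh measure of RNA quality described below as a further covariate the difference was 0.54 (limma, adjusted p = 0.580). Mex3b lay below the level filter, at 4.60 ± 0.13 (SD, n = 4) in WT and 5.03 ± 0.25 (SD, n = 3) in KO, with KO replicate 3 at 4.75 inside the WT range. Its difference in the fit over all probe sets was 0.47 (SE 0.10), with an adjusted p of 0.447 (limma). The exact permutation p of Mex3b was 0.0857, and 0.0556 within scan batch.

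**Figure D1:**
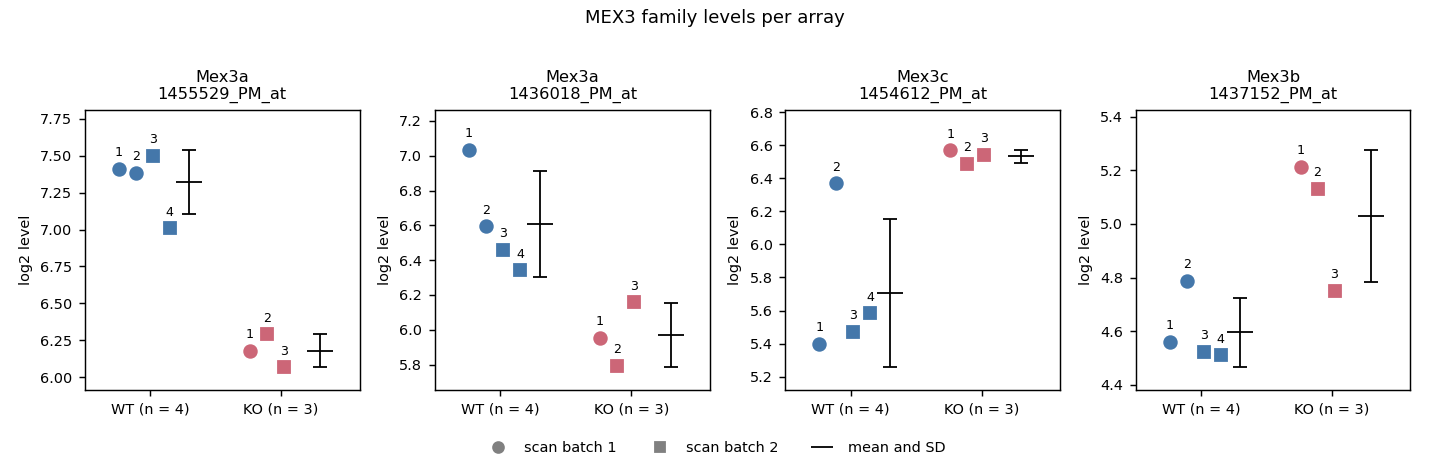
Log2 level of 4 probe sets of Mex3a, Mex3c and Mex3b on each array (points, with the replicate number above each and the shape showing the scan batch), with the mean and SD of WT (n = 4) and KO (n = 3). On the brighter Mex3a probe set the KO arrays sit between 6.07 and 6.29 and the WT arrays between 7.01 and 7.50, and WT replicate 2 lies at 6.37 for Mex3c.

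Apart from Mex3a, 7 named genes differed by at least 1 on the log2 scale, all with higher means in KO, and none of the 8 passed the threshold. Slc15a2, a peptide transporter, showed the largest difference, 1.81 (SE 0.45). It was 8.16 ± 0.22 (SD, n = 3) in KO and 6.22 ± 1.09 (SD, n = 4) in WT, where 3 arrays lay between 5.59 and 5.79 and WT replicate 4 at 7.85. Mptx1, a mucosal pentraxin of the intestinal crypt, was 2.11-fold higher at 6.59 ± 0.27 (SD, n = 3) in KO against 5.49 ± 0.24 (SD, n = 4) in WT, with every KO array above every WT array. Ddc, the decarboxylase of serotonin and dopamine synthesis, differed by 1.09 (SE 0.33), and Spink1, a trypsin inhibitor, by 1.01 (SE 0.45). For the next 2 genes the difference came from part of the KO arrays. Tgtp1, an interferon-inducible GTPase, stood at 8.20 and 7.30 in KO replicates 1 and 3 but at 4.64 in KO replicate 2. The alpha-defensin Defa31 stood at 10.7 in KO replicate 1 and at 7.69 and 7.75 in the others, and within scan batch 2 its difference turned to -0.21. Defa21 overlapped between the groups, at 8.40 ± 0.84 (SD, n = 3) in KO and 7.14 ± 1.28 (SD, n = 4) in WT. Probes for alpha-defensins may read several near-identical genes, so both defensin values are uncertain as to gene.

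Over all 12822 genes, limma called 0 genes at adjusted p under 0.05, and 0 at adjusted p under 0.10. At an unadjusted p under 0.05 there were 1462 genes, 916 higher and 546 lower in KO, where 641 are expected by chance. KO and WT arrays did not overlap for 758 genes (5.91%), of which 344 were higher and 414 lower in KO, and chance gives 5.71%. With 1 array left out, the difference of 54 of the 121 named genes moved by over 1.5 times or turned. Scan batch, a covariate of the fit, separated 0 genes at the same threshold. Leaving out WT replicate 2 gave 2 genes, Ddc and Mex3c, and leaving out WT replicate 4 gave 2 genes, Mex3a and Slc15a2. Fitting a weight to each array gave 1370 genes, 977 higher and 393 lower in KO. Those weights were lowest for KO replicate 1 (0.297) and highest for KO replicate 2 (3.04).

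**Figure D2:**
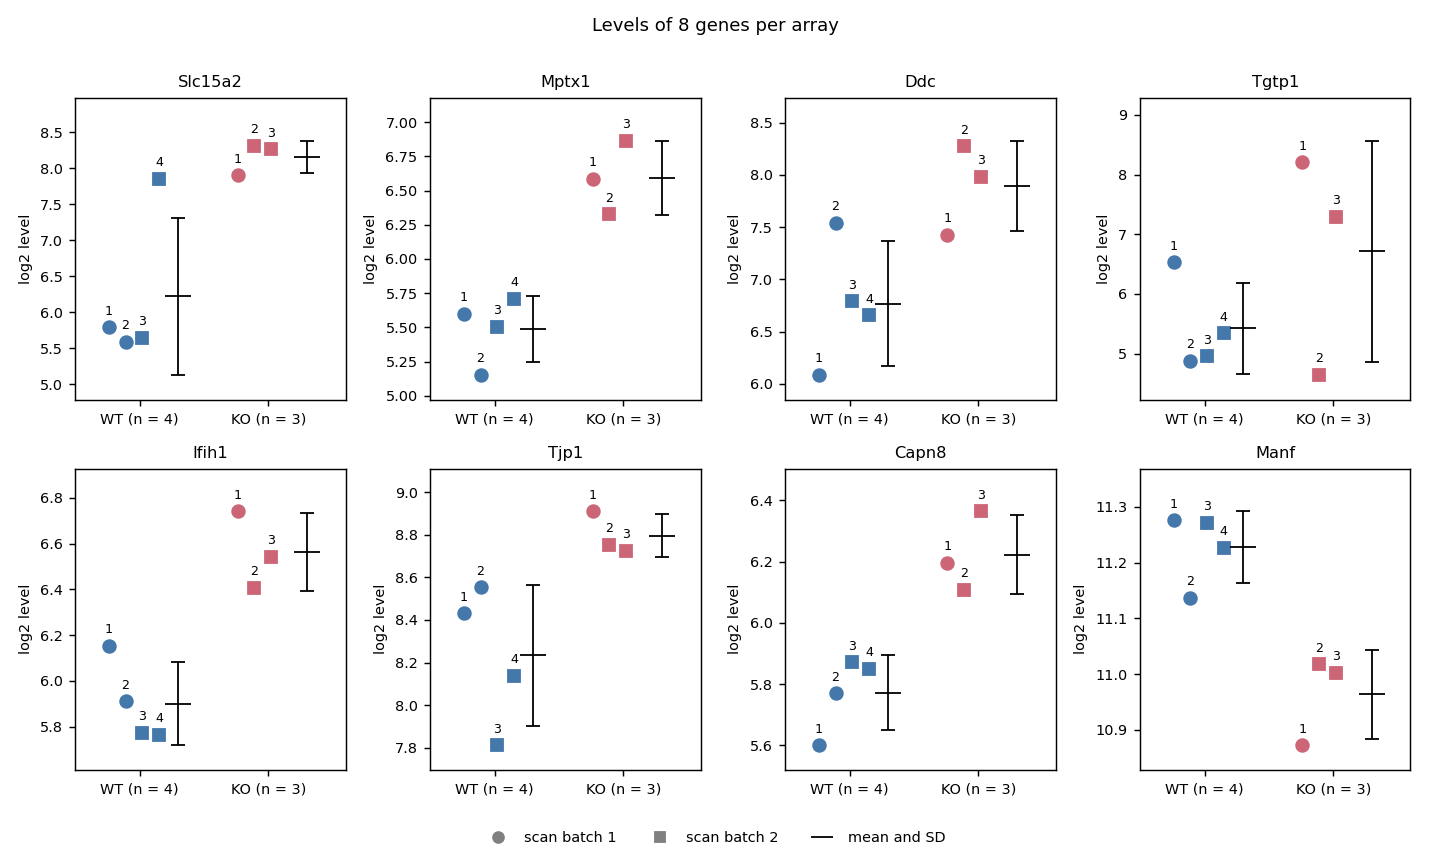
Log2 level of Slc15a2, Mptx1, Ddc, Tgtp1, Ifih1, Tjp1, Capn8 and Manf on each array (points with replicate numbers, shape by scan batch), with the mean and SD of WT (n = 4) and KO (n = 3). Slc15a2 of WT replicate 4 lies at 7.85, next to the KO arrays, and Tgtp1 of KO replicate 2 lies at 4.64, below the WT arrays.

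Genes of the mitochondrial respiratory chain stood slightly higher in KO. Of 44 tested members, 37 had a positive difference and the median log2 difference was 0.09. Complex I subunit Ndufa5 differed by 0.21 (SE 0.06), complex I subunits Ndufb3 and Ndufv1 by 0.25 (SE 0.09) and 0.16 (SE 0.06), and the cytochrome oxidase subunit Cox6c by 0.23 (SE 0.07); Ndufv1 turned to -0.11 with its probe set of largest variance. At unadjusted p under 0.05 there were 10 members higher and 1 lower, and 0 passed adjusted over the list alone or over all genes. The list was called by camera with its preset correlation (adjusted p = 9.05e-05), and not in the other test (adjusted p = 0.941 with an estimated correlation). Its mean per array was above the average of all arrays in the 3 KO arrays and, at 0.055, in WT replicate 2. The log2 difference between the 3' and 5' probe sets of Gapdh, used here as a measure of RNA quality, was lowest in the same 4 arrays. It was -0.131, -0.209, -0.121 and -0.121 in WT and -0.154, -0.213 and -0.239 in KO. A lower value of this difference means relatively less signal at the 3' end, so it is not by itself a sign of poorer RNA. With that difference as a further covariate, chosen after seeing the data, the call was lost (adjusted p = 0.183, median 0.03), as within scan batch 1 (adjusted p = 0.519, median 0.01), where the KO arm is 1 array, assumed to vary like the others. With 1 array left out the median was 0.07 to 0.14, the highest without KO replicate 1. Since that array is the only KO array of scan batch 1 and scan batch is in the fit, each difference given without it is the estimate from scan batch 2 alone.

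Markers of goblet cells and the secretory lineage, the mucus-producing branch of the epithelium, also stood higher in KO. Of 19 tested members 17 had a positive difference, with a median of 0.13. The mean of the list, relative to all arrays, was -0.50, 0.13, 0.10 and -0.25 in WT and -0.10, 0.33 and 0.30 in KO, so that WT replicate 1 stood lowest and KO replicate 1 lay below WT replicates 2 and 3. Capn8, a calpain of mucous cells, was 5.77 ± 0.12 (SD, n = 4) in WT and 6.22 ± 0.13 (SD, n = 3) in KO, and was the 1 member that passed adjusted over the list alone (limma, adjusted p = 0.0194), while 0 passed over all genes. Atoh1, the transcription factor that directs cells into the secretory lineage, differed by 0.63 (SE 0.27), Ccl6 by 0.90 (SE 0.37) and Sytl2 by 0.28 (SE 0.11), none of them past the threshold. The difference of Atoh1 was 0.38 without WT replicate 4 and 0.99 without KO replicate 1, and ranged from 0.080 to 0.99 over all alternatives. Camera called the list (adjusted p = 0.005), with adjusted p = 0.941 with an estimated correlation. The call was lost without WT replicate 4 (adjusted p = 0.342, median 0.06), with the lower 50% of levels left out (0.111, median 0.10), with members above the median level (0.0965), within scan batch 1 with its 1 KO array (0.843, median -0.07) and with the Gapdh difference as covariate (0.826, median -0.01). Without WT replicate 2 and without KO replicate 1 the median was higher, at 0.33 and 0.36. In a fit with no term for scan batch, made after seeing the data, the call held without WT replicate 4 (camera, adjusted p = 0.00164, median 0.10).

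Interferon-stimulated genes and genes of antigen presentation had higher means in KO, carried by 2 of the 3 KO arrays. Of 19 tested interferon-stimulated genes 17 had a positive difference (median 0.17), and of 14 genes of the MHC and antigen presentation list 12 did (median 0.24). Ifih1, a cytosolic sensor of double-stranded RNA, was 5.90 ± 0.18 (SD, n = 4) in WT and 6.56 ± 0.17 (SD, n = 3) in KO without overlap. It was the 1 interferon-stimulated gene that passed adjusted over the list alone (limma, adjusted p = 4.20e-04); over all genes its adjusted p was 0.142. Oasl2, Stat2 and Irf1 differed by 0.28 (SE 0.09), 0.41 (SE 0.17) and 0.27 (SE 0.12). With 1 array left out Stat2 was at 0.27 to 0.52 and Irf1 at 0.18 to 0.39, and Stat2 turned to -0.16 with its probe set of largest variance. Tapbp, which loads peptide onto MHC class I, differed by 0.27 (SE 0.06) and was the 1 antigen presentation gene that passed adjusted over the list alone (limma, adjusted p = 0.0288), with 0 over all genes. The protease Ctss differed by 0.62 (SE 0.18), and the MHC genes H2-Aa and H2-K1 by 0.21 (SE 0.13) and 0.22 (SE 0.13). H2-Aa was at 0.10 without KO replicate 3 and H2-K1 at 0.10 without KO replicate 1, with lowest values of 0.028 and 0.044 over all alternatives, and Ctss was at 0.41 without WT replicate 4. Camera called both lists (adjusted p = 0.005 each), with adjusted p = 0.941 with an estimated correlation for both. The mean of the interferon-stimulated list, relative to all arrays, was 0.39, -0.21 and 0.17 in the KO arrays and 0.27, -0.33, -0.12 and -0.16 in the WT arrays. Without KO replicate 1, which leaves the estimate of scan batch 2 (medians 0.12 and 0.15), the adjusted p of both lists was 0.730, and it was 0.574 for both when only scan batch 2 was fitted. With no term for scan batch, so that all WT arrays count, it was 0.618 and 0.364 without KO replicate 1 (0.016 and 0.043). With the term for scan batch kept, it was 0.158 and 0.116 without WT replicate 2 (0.08 and 0.16), and 0.699 and 0.706 with array weights (0.04 and 0.03). Without KO replicate 2 the medians were 0.30 and 0.31. On the 5 arrays without Y-linked signal, a choice made after seeing the data, the medians turned to -0.07 and -0.02 (camera, adjusted p = 0.902 and 0.653), while with the Gapdh difference as covariate they were 0.41 and 0.37 (adjusted p = 1.59e-08 and 4.43e-08). The interferon call alone was also lost with the mean of all probe sets (0.0732, median 0.12), the probe set of largest variance (0.297, median 0.09) and members above the median level (0.0855). With the lower 50% of levels left out it just missed the threshold (0.0508), although the median was larger, at 0.27. Leukocyte markers, given beside these lists because leukocytes express many of their members, had a median difference of -0.01 over 21 tested genes (camera, adjusted p = 0.812).

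Genes of the unfolded protein and integrated stress response stood lower in KO. Of 27 tested members 21 had a negative difference and the median was -0.10. Manf, a secreted protein induced by stress of the endoplasmic reticulum, was 11.23 ± 0.06 (SD, n = 4) in WT and 10.96 ± 0.08 (SD, n = 3) in KO, and was the 1 member that passed adjusted over the list alone (limma, adjusted p = 0.0315), with 0 over all genes. The endoplasmic reticulum proteins Sdf2l1 and Pdia6 differed by -0.41 (SE 0.11) and -0.23 (SE 0.08), and Phgdh, an enzyme of serine synthesis, by -0.28 (SE 0.09), each with all KO arrays below all WT arrays. KO replicate 1 was the lowest for all 3, and without it, in scan batch 2, Sdf2l1 was at -0.21 and Pdia6 at -0.13. Camera called the list (adjusted p = 0.0231), with adjusted p = 0.941 with an estimated correlation. The call was lost with a smaller median in the estimate of scan batch 2 (median -0.05), whether KO replicate 1 was left out (adjusted p = 0.785) or only that batch was fitted (0.687), with array weights (0.659, -0.04), with the mean of all probe sets (0.0842, -0.06) and with the probe set of largest variance (0.174, -0.06). It was also lost without WT replicate 1 (0.129) and without WT replicate 2 (0.0844), where the median stayed near its value, at -0.08 and -0.10. With no term for scan batch the adjusted p was 0.0679 without KO replicate 1 (median -0.08). The call held with the Gapdh difference as covariate (camera, adjusted p = 5.31e-04, median -0.11). It also held on the 5 arrays without Y-linked signal (camera, adjusted p = 0.0331, median -0.09). Both of these settings were chosen after seeing the data. Within scan batch 1, with its 1 KO array, the median was -0.18. KO replicate 1 had the lowest list mean, at -0.13 relative to all arrays, and WT replicate 1 the highest, at 0.13. Immediate early and dissociation stress genes also had mostly negative differences, 23 of 29 (camera, adjusted p = 0.132), and their mean was lowest in KO replicate 1, at -0.27, and stood at 0.14 in WT replicate 1 and 0.19 in KO replicate 3. The difference between the 3' and 5' probe sets of actin stood apart in KO replicate 1, at -0.301 against -0.515 to -0.429 in the other arrays.

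**Figure D3:**
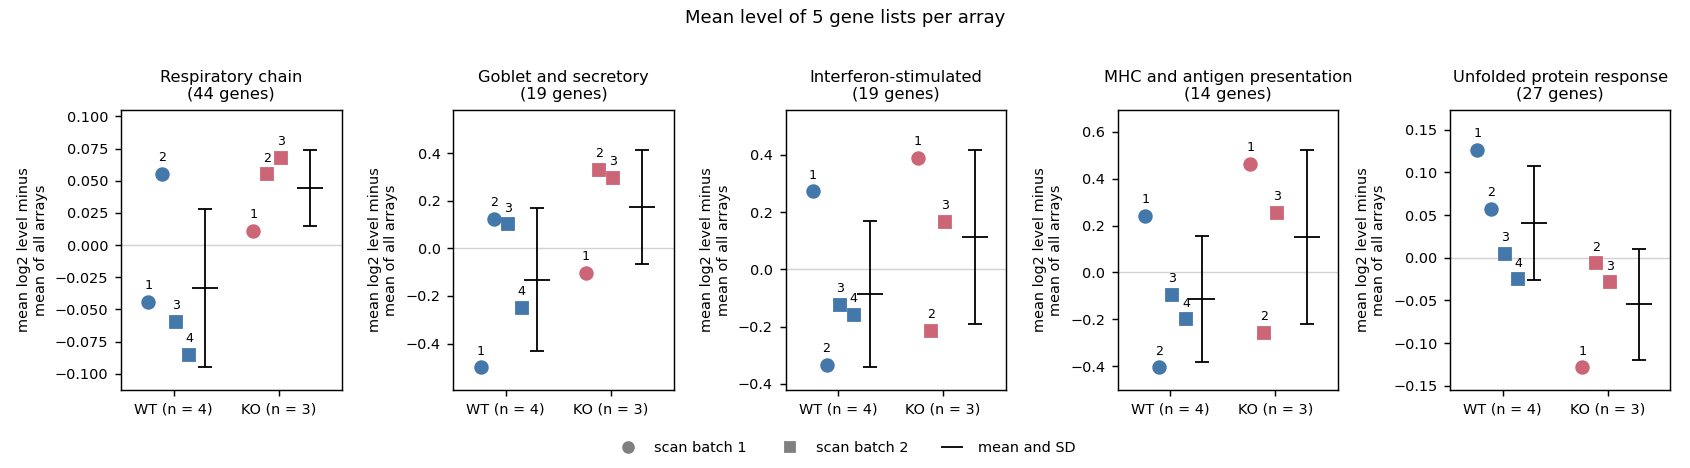
Mean log2 level of the 5 gene lists called by camera on each array, minus the mean of all 7 arrays (points with replicate numbers, shape by scan batch), with the mean and SD of WT (n = 4) and KO (n = 3). The groups overlap in every panel; in the interferon panel KO replicate 1 lies at 0.39 and KO replicate 2 at -0.21.

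In all, camera with its preset correlation called 5 of 30 lists, 4 higher and 1 lower in KO. Within scan batch 1, with its 1 KO array, it called 6, of which 2 were higher and 4 lower, and with the Gapdh difference as covariate also 6, of which 2 were higher and 4 lower. With an estimated correlation 0 lists were called, and 0 by fry, which tests whether a list's genes move one way (smallest adjusted p = 0.416) or in either direction (smallest adjusted p = 0.0609). An exact permutation test on each list's mean per array cannot decide this, since its smallest p of 0.0286 would have to be reached by 18 of the 30 lists before any passed adjustment. Camera with an estimated correlation and fry were not run on the simulated data. Whether they would find a shifted list with these few arrays is therefore not known.

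Among the lists that camera did not call, deep crypt secretory and Paneth cell markers came nearest (adjusted p = 0.0726, median 0.16, 12 tested). Their mean per array, relative to all arrays, was 0.052, 0.089 and 0.242 in KO and -0.220 to -0.002 in WT. Of the 12 members 8 had a positive and 4 a negative difference, and the list mean leans on Mptx1 at 1.08 and Reg3g at 0.90. Of the 30 lists only this one and the endothelial markers had means that did not overlap between the groups (exact permutation p = 0.0286 each, and 0.111 each within scan batch), where chance gives 1.71 lists, and neither was called by camera. Mptx1 and Reg3g, a secreted antimicrobial lectin, passed adjusted over the list alone (limma, adjusted p = 0.00165 and 0.0459), and 0 passed over all genes. Lyz2 differed by 0.39 (SE 0.15) and Mmp7, a Paneth cell protease, by 0.21 (SE 0.09). Lgr5-type stem cell markers did not separate the groups (20 tested, median -0.03, adjusted p = 0.865), with Lgr5 itself at -0.07 (SE 0.16), Rgmb at 0.25 (SE 0.09), Msi1 at -0.53 (SE 0.19), Hopx at 0.36 (SE 0.15; -0.049 within scan batch 1) and Nkd1 at -0.24 (SE 0.11). Wnt/beta-catenin targets had a median of -0.07 over 29 genes (adjusted p = 0.264), with Ccnd2 and Lef1 at -0.20 (SE 0.05) and -0.35 (SE 0.12) and Dkk2 at 0.46 (SE 0.12). Colonocyte markers had a median of 0.07 over 28 genes (adjusted p = 0.267); among them the secreted peptides Guca2a and Guca2b differed by 0.85 (SE 0.30) and 0.60 (SE 0.23), Hsd17b2 by 0.53 (SE 0.23) and the water channel Aqp8 by -0.11 (SE 0.08). Enteroendocrine markers (14 tested, median 0.03, adjusted p = 0.865) and tuft cell markers (11 tested, median -0.07, adjusted p = 0.377) held no member at unadjusted p under 0.05. The enteroendocrine members of smallest p were Chgb at 0.46 (SE 0.36), Sct at -0.10 (SE 0.08), Chga at 0.11 (SE 0.09) and Scg3 at -0.10 (SE 0.09), with Chgb and Scg3 turning within scan batch 1 (-0.51 and 0.030) and Chgb with the Gapdh covariate (-0.089), and the tuft cell members Ltc4s at -0.13 (SE 0.06), Plcb2 at -0.09 (SE 0.06), Gng13 at -0.09 (SE 0.08) and Dclk1 at -0.05 (SE 0.05). With 1 array left out, Chgb ranged from 0.064 to 1.10. In these stem cell, Wnt, colonocyte, enteroendocrine and tuft cell lists 0 members passed adjusted over the list alone or over all genes.

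Genes of proliferation did not separate the groups. DNA replication genes had a median of -0.02 over 27 genes (camera, adjusted p = 0.782), with Slbp at 0.35 (SE 0.12), Mcm4 at 0.32 (SE 0.13), Cdt1 at 0.28 (SE 0.12) and Pola1 at 0.20 (SE 0.08). Of these, Slbp and Cdt1 turned to -0.026 and -0.17 with their probe sets of largest variance, and Mcm4 to -0.018 within scan batch 1. Mitosis genes had a median of -0.02 over 29 (adjusted p = 0.865), with the ubiquitin-conjugating enzyme Ube2c at -0.35 (SE 0.08), Ckap2 at -0.23 (SE 0.10), Bub1b at -0.18 (SE 0.10) and Ttk at 0.18 (SE 0.10). Retinoic acid and RXR signalling genes had a median of 0.01 over 18 (adjusted p = 0.865), with the receptors Rxra and Rara at -0.24 (SE 0.10) and -0.23 (SE 0.12), Dhrs3 at -0.17 (SE 0.13) and Ncoa3 at 0.16 (SE 0.13), the last turning to -0.046 within scan batch 2 and to -0.015 with the mean of all probe sets. PPAR target and fatty acid oxidation genes had a median of -0.01 over 17 (adjusted p = 0.865), with the acyl-CoA dehydrogenases Acadl and Acadm at 0.36 (SE 0.10) and 0.30 (SE 0.13), Slc25a20 at 0.17 (SE 0.10) and Cpt2 at -0.18 (SE 0.10). Fetal-like and regenerative epithelium genes (18 tested, median 0.03, adjusted p = 0.865) included Tnfrsf12a at -0.31 (SE 0.10), Ankrd1 at -0.22 (SE 0.10), Ccn1 at -0.54 (SE 0.32) and Anxa1 at 0.40 (SE 0.18). With 1 array left out, Ccn1 ranged from -0.86 to -0.12. Genes of NF-kB and inflammatory mediators had a median of 0.03 over 25 (adjusted p = 0.548), with the chemokine Cxcl2 at 0.43 (SE 0.14) and Icam1 at 0.31 (SE 0.13), and with Nos2 at -0.13 (SE 0.05) and Duoxa2 at -0.14 (SE 0.06). Targets of p53 (24 tested, median -0.02, adjusted p = 0.976) included Perp at 0.29 (SE 0.09), Tnfrsf10b at -0.29 (SE 0.11), Psrc1 at -0.41 (SE 0.17) and Btg2 at -0.43 (SE 0.17). Glycolysis and hypoxia genes had a median of -0.06 over 28 (adjusted p = 0.332), with Pfkl at -0.34 (SE 0.09), Ldha at -0.11 (SE 0.05), the glucose transporter Slc2a1 at -0.32 (SE 0.14) and Higd1a at 0.19 (SE 0.10; -0.015 within scan batch 1). Cholesterol synthesis genes (18 tested, median 0.00, adjusted p = 0.865) included Dhcr7 at 0.26 (SE 0.09), Msmo1 at -0.28 (SE 0.13), Insig1 at -0.26 (SE 0.14) and Fdps at -0.16 (SE 0.09). In these 9 lists 0 members passed adjusted over the list alone or over all genes. For the stem cell, DNA replication, retinoic acid, PPAR, cholesterol, ribosomal protein and fibroblast lists, the median and the mean or the test differed in sign.

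Lists read as measures of the sort, the dissociation and the RNA were not called either. Epcam, the protein used in the sort, differed by 0.00 (SE 0.05), and the epithelial identity list had a median of 0.07 over 19 genes (camera, adjusted p = 0.284). Tjp1, a tight junction scaffold, was 8.23 ± 0.33 (SD, n = 4) in WT and 8.80 ± 0.10 (SD, n = 3) in KO and was the 1 member of that list to pass adjusted over the list alone (limma, adjusted p = 0.0149), with 0 over all genes. Next in that list were F11r at 0.30 (SE 0.10), Tspan8 at 0.58 (SE 0.21) and Cldn4 at -0.20 (SE 0.08). Immediate early and dissociation stress genes had a median of -0.05 over 29 genes (adjusted p = 0.132; 0 members adjusted over the list alone), with Atf3 at -0.54 (SE 0.18), Btg2 at -0.43 (SE 0.17), Fosb at -0.51 (SE 0.22) and Hsp90aa1 at -0.14 (SE 0.07). Ribosomal protein genes had a median of -0.01 over 39 (adjusted p = 0.865; 0 members adjusted over the list alone), with Rplp0 at -0.13 (SE 0.04), Rpl28 at -0.11 (SE 0.04), Rpl19 at -0.12 (SE 0.05) and Rpl13 at 0.14 (SE 0.07), the last turning to -0.024 with the mean of all probe sets and to -0.18 with that of largest variance. Fibroblast and smooth muscle markers had a median of -0.01 over 20 (adjusted p = 0.865), and the 1 member that passed adjusted over the list alone was Vim, at -0.29 (SE 0.06; limma, adjusted p = 0.0319). Fbln1 was at -0.43 (SE 0.15), while Thy1 and Col4a1 were at 0.17 (SE 0.07) and 0.47 (SE 0.20). Endothelial markers had a median of -0.02 over 13 (adjusted p = 0.284), with a mean per array of -0.066 to -0.004 in KO and 0.016 to 0.042 in WT, and the 1 member that passed adjusted over the list alone was Cdh5, at -0.41 (SE 0.09; limma, adjusted p = 0.0296), followed by Flt1 at -0.32 (SE 0.14), Prox1 at -0.10 (SE 0.05) and Plvap at -0.08 (SE 0.06). Over all genes 0 members of either list passed. Enteric neuron and glia markers (9 tested, median -0.06, adjusted p = 0.548), erythroid markers (5 tested, median -0.10, adjusted p = 0.377) and leukocyte markers held 0 members adjusted over the list alone. Their 4 members of smallest p were Sox10 at -0.11 (SE 0.09), Nos1 at -0.10 (SE 0.09), Elavl3 at -0.09 (SE 0.09) and Ret at -0.06 (SE 0.06) among neuron and glia markers, and Alas2 at -0.12 (SE 0.07), Klf1 at -0.13 (SE 0.11), Slc4a1 at -0.10 (SE 0.10) and Epb42 at -0.08 (SE 0.08) among erythroid markers. Among leukocyte markers they were Cd79a at -0.12 (SE 0.08), Laptm5 at -0.10 (SE 0.07), Csf1r at -0.12 (SE 0.08) and Ighm at -0.12 (SE 0.10). Within scan batch 1 Sox10, Nos1, Elavl3, Klf1, Epb42 and Ighm turned (0.038, 0.083, 0.010, 0.060, 0.090 and 0.044), and Laptm5 did so with its probe set of largest variance (0.10). The 3 sex-linked genes tested did not separate the groups (adjusted p = 0.865; 0 members adjusted over the list alone), and the Y-linked Eif2s3y was 8.92 in WT replicate 2 and 9.02 in KO replicate 3 and between 4.17 and 4.29 in the other arrays. It differed by 0.56 (SE 1.54), Kdm5d by 0.41 (SE 0.92) and Xist by -0.82 (SE 1.77), each turning in several alternatives. The MEX3 family list as a whole had an adjusted p of 0.812, its members going opposite ways.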

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

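Tests chosen only after the result was seen are those of WT replicate 2 (mislabelling, sex, scan batch and RNA quality), of leukocyte RNA and of a single KO array behind the interferon-stimulated list, of sex and the first principal component for Mex3c, and the count of splits for genes past the adjusted threshold; the other counts of splits were planned. Of 153 sets of 4 WT values checked, 18 had 1 array far from the other 3 relative to their range, where chance gives about 1 in 20, or 7.65. That array was WT replicate 1 in 7 of the 18 and WT replicate 2 in 7, of which 4 are sex-linked values. Exact ties between the other arrays make such gaps more frequent in these data.

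The values that stood apart among named genes were Slc15a2 at 7.85 in WT replicate 4 (others 5.59 to 5.79), Spink1 at 6.27 in WT replicate 1 (others 8.19 to 8.52) and Chgb at 6.80 in WT replicate 3 (others 7.41 to 7.49). In WT replicate 1, Chga stood at 6.49 (others 6.80 to 6.81), Cpt2 at 8.99 (others 8.61 to 8.66) and Dhcr7 at 9.19 (others 8.94 to 8.97). In WT replicate 4, Dclk1 stood at 5.69 (others all 5.61) and Icam1 at 7.78 (others 8.22 to 8.31). In WT replicate 2, Ncoa3 stood at 8.29 (others 8.48 to 8.52), Tnfrsf12a at 10.2 (others 10.50 to 10.54) and H2-Aa at 7.65 (others 7.91 to 7.96). The sex-linked genes of WT replicate 2 stood at 6.89 for Xist (others 11.08 to 11.28), 7.54 for Kdm5d (others 4.71 to 4.88) and 8.92 for Eif2s3y (others 4.17 to 4.24). Among list means relative to all arrays, WT replicate 1 stood apart for Wnt/beta-catenin targets at 0.057, enteroendocrine markers at -0.254 and p53 targets at 0.157, and WT replicate 2 for the sex-linked genes at 0.778.

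WT replicate 2 lay nearer to the KO arrays than to the other WT arrays: with each gene centred on its mean, which pulls such values below 0, it correlated across genes (not independent replicates) at 0.278 with KO replicate 3, 0.112 with KO replicate 2 and -0.150 with KO replicate 1, and at -0.267 to -0.425 with the WT arrays. The KO arrays did not form a single group either. KO replicate 1 correlated at 0.102 with WT replicate 1, but at -0.219 and -0.153 with KO replicates 2 and 3. A KO sample under a WT label is argued against by Mex3a, whose level in WT replicate 2 lay 3.42 and 10.8 KO SDs above the KO mean on its 2 probe sets. Sex as the only cause is argued against for these arrays, although KO replicate 3, the best match of WT replicate 2, also carried Y-linked signal. Over autosomal genes WT replicate 2 correlated better with KO arrays without Y-linked signal than with any WT array. The smallest such difference was 0.126 (95% interval 0.080 to 0.166). Scan batch is argued against too, since the best match of WT replicate 2 in the other batch exceeded that in its own by 0.427 (0.324 to 0.544). The intervals in this paragraph come from resampling genes with the arrays held fixed, so they do not measure the spread between samples. RNA quality may set these arrays apart, since the 3' to 5' difference of Gapdh was -0.209 in WT replicate 2, -0.154, -0.213 and -0.239 in the KO arrays and -0.131 to -0.121 in the other WT arrays. It cannot be told apart from the make-up of the tumours (stage, size or cell types, untested): without the slope of each gene on Gapdh the difference in correlation turned to -0.425 (-0.484 to -0.373), but the slope on actin gave -0.429 and 18.8% of the 5040 orders of the Gapdh values one as low.

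Mex3c was higher in KO, with WT replicate 2 between the groups. Sex is argued against as the only cause, since among the 5 arrays without Y-linked signal the difference was 1.05 (SE 0.09). That fit leaves out WT replicate 2, the WT array nearest to KO. The arrays with Y-linked signal stood close together, at 6.37 in WT replicate 2 and 6.54 in KO replicate 3. A difference that depends on sex is therefore not excluded. The axis of the first principal component, where WT replicate 2 scores 10.4, the KO arrays 1.98 to 14.5 and the other WT arrays -14.5 to -8.21, cannot be told apart from genotype: with it as covariate the difference was 0.42 (SE 0.19, 95% interval -0.027 to 0.87), against 0.87 (SE 0.21) without, and the scores themselves follow genotype in part. A candidate explanation left open is a response of Mex3c to the loss of Mex3a, a hypothesis found and read on the same arrays. Probes shared between the paralogs were not tested, and Mex3a and Mex3c moved in opposite directions.

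The interferon-stimulated list was higher in KO, and single arrays could account for its call: with no term for scan batch, so that all WT arrays count, the adjusted p was 0.618 without KO replicate 1 (median 0.016, against 0.18 with all arrays) and 0.410 without WT replicate 2 (median 0.08). Leukocyte RNA among the sorted cells cannot be told apart from a change in the tumour cells by these arrays. The leukocyte markers had a median difference of -0.013 (95% interval -0.050 to 0.010). That interval comes from resampling the 21 genes with the arrays held fixed and does not measure the spread between samples. Moreover, 0 of the 21 tested lay above the median level of all genes, so a small share of leukocytes would hardly show. The most abundant of them named here, Csf1r and Cd79a, stood at 6.84 and 6.63 in KO, and the sort for Epcam should remove leukocytes. A genotype effect on interferon signalling stays open, though the list mean of KO replicate 2 was -0.21 and the median turned to -0.07 on the 5 arrays without Y-linked signal.

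Other splits of the 7 arrays bear on the counts over all genes; 34 of the 35 could be fitted with scan batch, the exception being the split that equals scan batch. The real split gave 0 genes past the adjusted threshold, a number that each of the 34 reaches whatever it holds, so this count says nothing about chance; the highest other split gave 80. At unadjusted p under 0.05 the real split gave 1462 genes and 3 of 34 splits gave as many, up to 2564. With array weights it gave 1370 genes and 2 of 34 splits gave as many, up to 2085. For lists called by camera it gave 5 and 18 of 34 splits gave as many, up to 12. Chance can be excluded for none of these last 3 counts. The split that called 80, 2564 and 2085 genes sets WT replicates 1, 3 and 4 against WT replicate 2 with the KO arrays, which points to a structure of the samples beyond genotype. For Mex3a alone the real split had the smallest p of the 34, 2.17e-05 against 0.00135 for the next.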

How the results depend on the processing

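The term for sex, the fit on the 5 arrays without Y-linked signal, the Gapdh 3' to 5' difference as covariate and the fit on all probe sets were chosen only after the result was seen. The count of 0 genes past the threshold held under 24 of 28 alternatives; it was 0 to 2 with 1 array left out (2 without WT replicate 2 and 2 without WT replicate 4), 1370 with array weights (917 of them at unadjusted p under 0.05 without weights) and 1462 without adjustment. The cause was not tested, and the threshold itself accounts for the 1462. The Mex3a difference kept its direction under all 24 alternatives (-1.27 to -0.87), was -1.27 to -1.02 with 1 array left out, and passed the threshold at -1.27 without WT replicate 4 and at -1.18 with array weights. Camera called 5 lists, and 2 to 9 with 1 array left out, 6 within scan batch 1 (2 higher and 4 lower in KO), 2 within scan batch 2, 6 with the Gapdh covariate (2 higher and 4 lower), 3 with the lower 50% of levels left out, 3 with members above the median level, 2 with array weights, and 0 with an estimated correlation, 0 with fry in 1 direction and 0 with fry in either. With 1 array left out, the adjusted p ranged from 7.29e-07 to 0.00159 for the respiratory chain, 4.49e-06 to 0.342 for goblet markers, 4.36e-07 to 0.730 for interferon-stimulated genes, 3.40e-07 to 0.730 for antigen presentation and 0.00299 to 0.785 for the unfolded protein response. Leaving out KO replicate 1, the only KO array of scan batch 1, gives the differences of scan batch 2 and is no separate alternative for them. With an estimated correlation it was 0.941 for all 5. In that order fry gave 0.501, 0.791, 0.791, 0.791 and 0.501 for 1 direction, and 0.284, 0.502, 0.366, 0.502 and 0.178 for either. Within scan batch 1 it was 0.519 for the respiratory chain and 0.843 for goblet markers; within scan batch 2 it was 0.574 for interferon-stimulated genes, 0.574 for antigen presentation and 0.687 for the unfolded protein response. Array weights gave 0.699, 0.706 and 0.659 for those 3 lists. The lower 50% of levels left out gave 0.111 for goblet markers and 0.0508 for interferon-stimulated genes, and members above the median level gave 0.0965 and 0.0855. The mean of all probe sets gave 0.0732 for interferon-stimulated genes and 0.0842 for the unfolded protein response, and the probe set of largest variance 0.297 and 0.174. The Gapdh covariate gave 0.183 for the respiratory chain and 0.826 for goblet markers, where the median turned to -0.01. On the 5 arrays without Y-linked signal interferon-stimulated genes had 0.902 and antigen presentation 0.653, with medians of -0.07 and -0.02 against a positive direction of the test. Among named genes 34 of 2849 alternatives turned the direction. Within scan batch 1, where 1 KO array is assumed to vary like the others, Chgb was at -0.51, Eif2s3y at -2.28, Kdm5d at -1.21, Higd1a at -0.015, Hopx at -0.049, Mcm4 at -0.018, Elavl3 at 0.010, Epb42 at 0.090, Ighm at 0.044, Klf1 at 0.060, Nos1 at 0.083, Scg3 at 0.030, Sox10 at 0.038 and Xist at 2.29. Within scan batch 2 Defa31 was at -0.21 and Ncoa3 at -0.046. With the mean of all probe sets Ncoa3 was at -0.015 and Rpl13 at -0.024; with the probe set of largest variance Cdt1 was at -0.17, Laptm5 at 0.10, Ndufv1 at -0.11, Rpl13 at -0.18, Slbp at -0.026 and Stat2 at -0.16. With the Gapdh covariate Chgb was at -0.089, Eif2s3y at -2.34, Kdm5d at -1.29 and Xist at 2.26. Xist was at 0.22 on the 5 arrays without Y-linked signal. With 1 array left out, Defa31 ranged from -0.21 to 1.49, Eif2s3y from -1.10 to 2.45, Kdm5d from -0.59 to 1.49, Ncoa3 from -0.046 to 0.23 and Xist from -2.90 to 1.30. The cause was not tested, beyond the fewer arrays or other probe sets used. Of the 25 lists not called, 19 changed direction in at least 1 of their alternatives (68 of 691) and 5 were called in some (23 of 691), the deep crypt list among them. No paired analysis was possible because the labels give no replicate number shared by the groups. Signal over background was not measured, so levels near the filter are the least certain.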

Other observations

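The tests on the spread of neighbouring genes, on RNA quality for the respiratory chain and on the direction of the neighbours of Mex3a were chosen only after the result was seen; those on the level of respiratory chain genes, on the number of changed neighbours of Mex3a and on the Hox genes were written before their results.

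Posterior Hox genes, which keep the position of a cell along the gut, differed between arrays of the same genotype. Hoxd13 was 7.06 in WT replicate 1 and 8.28 to 9.39 in the other 6 arrays, Hoxd11 was 7.45 against 8.78 to 9.24, and Hoxd9 was 7.66 against 8.98 to 9.76. Between KO and WT the log2 differences were 0.80 (SE 0.41), 0.34 (SE 0.33) and 0.58 (SE 0.31), none past the threshold (limma, adjusted p = 0.474, 0.673 and 0.488). A hypothesis is a more proximal origin of that tumour tissue, which may lie nearer the start of the colon. Of 5 other posterior Hox genes tested, 2 were at their lowest in WT replicate 1 (Hoxb13 and Hoxd12), against 1 in 7 by chance (one-sided exact binomial p = 0.152), which does not decide it; Hoxd12 belongs to the same cluster, and Hoxb13 moved little, from 11.45 to 11.49.

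The arrays also differed in sex-linked genes. WT replicate 2 and KO replicate 3 carried Y-linked signal, with Kdm5d at 7.54 and 7.82 against 4.71 to 4.92 in the others. On the 3 probe sets of Xist, the RNA that silences an X chromosome in females, WT replicate 2 stood at 5.68, 5.81 and 6.89 and KO replicate 3 at 4.80, 5.19 and 5.05, while the other arrays lay between 9.43 and 11.45.

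The shift of respiratory chain genes was set against 10000 random lists matched on mean level, because abundant genes can shift together on arrays. The median moderated t of the list lay at percentile 100 of the matched lists, whose own median was -0.137, so level alone is argued against as its cause. That comparison treats genes as independent, which the estimated correlation of 0.284 between the list's genes contradicts. A factor that follows the Gapdh 3' to 5' difference could account for the shift. With that covariate the difference in the list's mean per array went from 0.082 (SE 0.042) to 0.020 (SE 0.013, 95% interval -0.021 to 0.061). The difference in the list's mean thus shrank, and its SE did not grow. Camera does not use that SE, so why its call ended was not tested. RNA quality may be such a factor, but with the actin difference as covariate the list's difference was 0.103 (SE 0.051). The Gapdh differences spanned only -0.239 to -0.121 on the log2 scale, and those of actin ranked the arrays differently. The Gapdh difference itself was lower in KO than in 3 of the 4 WT arrays, so an effect of genotype stays open.

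A segment of chromosome carried along with the targeted Mex3a allele may change nearby genes. Of the 50 nearest measured neighbours, 4 were at unadjusted p under 0.05, against 11.4% of other genes (one-sided Fisher's exact p = 0.836), so no excess in number was seen. All 4 were lower in KO, among them the next 2 measured genes on 1 side, Rab25 at -0.58 (SE 0.12) and Lamtor2 at -0.24 (SE 0.10), neither past the threshold over all genes (limma, adjusted p = 0.329 and 0.434). Of the 50 neighbours 37 had a negative difference, a number reached by 5.69% of 11796 windows of as many neighbouring genes (central 95% 18 to 38), so an effect of the segment on their direction cannot be told apart from chance.

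Segregating chromosome segments (genetic background) could leave blocks of neighbouring genes that vary together. Among the 100 autosomal genes of largest SD over the arrays, 11 pairs lay within 3 gene positions of each other, more than in any of 10000 random sets matched on level (permutation p = 1e-04, the smallest they can give). Several of these pairs are gene families or shared responses, such as Hoxd13 with Hoxd11, H2-Q4 with H2-Q5, Reg3b with Reg3g, and Psmb8 with H2-Ab1. Not all pairs varied together over the arrays: Reg3b with Reg3g correlated at 0.03 and Defa21 with Defa31 at 0.08. Without pairs that shared the first 3 characters of their symbols or 1 of the fixed lists, 5 remained. Random sets held 0 to 6 in the central 95% (permutation p = 0.079). That rule may leave related pairs in: Tgtp1 with Ifi47 (correlation 0.93) and a pair of predicted transcripts (0.95) were kept. Another kept pair of predicted transcripts correlated at -0.24. Background therefore cannot be told apart from shared regulation by this test.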
